A study of Mus musculus with 24 samples.

How the data were processed

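Kidney RNA was measured in 24 mouse libraries, 4 in each of 6 groups: Pld4 wild type (WT) and Pld4 knockout (KO) at day 0 (control) and at day 5 and day 10 of unilateral ureteral obstruction (UUO). Per the labels' protocols, total RNA was extracted with TRIzol and 1 ug of it went into TruSeq stranded mRNA libraries, which were sequenced on a NextSeq500. The labels list bcl2fastq 2.16, STAR 2.5 and Cufflinks with no version, and the mm9 genome. The authors deposited a file of raw counts per gene and a file of FPKM per gene. The tool and the annotation behind the counts, and whether strand was used, are not stated per the labels, so overlapping and antisense genes cannot be told apart, and near-identical copies such as the Serpina1 genes are uncertain. The counts are whole numbers for 23955 symbols, the FPKM values cover 23953, and 23894 symbols are in both. Total counts per library ran from 9800888 to 22542866. Group names, day and replicate number of all columns come from the labels; age, sex, strain, allele and surgery batch are not given there.

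All tests used the deposited counts. Genes were kept by filterByExpr of edgeR 4.0.16 on the 6 groups (minimum count 10, minimum total 15), which left 15080. Libraries were scaled by TMM, and 1 model with 6 group means was fitted to all 24 libraries, with 18 residual degrees of freedom (edgeR's quasi-likelihood test, robust). Benjamini-Hochberg adjustment was made per comparison over the genes tested, at a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. There were 11 comparisons: KO against WT at each day, each UUO day against day 0 in each genotype, day 10 against day 5 in each genotype, and the difference between genotypes in the response at day 5 and at day 10. CPM values are scaled to the total count times the TMM factor. Where a group held no count, a lower bound against 3 counts over the group is given. With 1 to 3 counts, the ratio is given with a 95% counting interval. Both use counts pooled over the 4 libraries of a group and hold no spread between libraries.

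Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), for lists with at least 5 tested members, adjusted over the lists within a comparison. Camera sets a list against all other genes tested, so a list can miss the threshold though its genes changed. The 37 lists were written before the data were examined, as were the groups, the tests, the other settings to try and the rule for naming genes. The lists tested were collagens, other extracellular matrix, myofibroblast and fibroblast, TGF-beta pathway, matrix metalloproteinases, TIMPs and plasminogen system, cathepsins, neutrophil, serpins and other protease inhibitors, Th1, Th2, interferon response, endosomal nucleic acid sensing, T cell, NK and cytotoxic, B and plasma cell, macrophage, dendritic cell, chemokines and inflammatory cytokines, complement, tubular injury, proximal tubule, loop, distal tubule and collecting duct, podocyte, endothelium, cell cycle, fatty acid oxidation, phospholipase D family, genes neighbouring Pld4, and urothelium. Another 7 had fewer than 5 tested members and were not tested: mast cell, digestive serine proteases, adipocyte, adrenal, erythroid, skeletal muscle and sex-linked genes. A list score is the mean log2 CPM of its tested members. Genes are named by rule: Pld4, Elane, Serpina1a, Col1a1, Col3a1, Fn1, Acta2 and Tgfb1; up to 8 genes with the largest rise and 8 with the largest fall, with a mean log2 CPM of at least 1, groups that do not overlap and no placeholder symbol; and up to 4 members of each described list with the lowest adjusted p. Xist, Ddx3y, Eif2s3y, Kdm5d, Malat1, Neat1, Clk1, Clk4, Ccnl1, Ccnl2, S100a8, Cxcr2 and Slc34a1 per library, and genes called at all 3 days, were chosen after the values were seen.

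The other settings were RLE factors, no low-count filter, a filter of CPM of at least 1 in at least 8 libraries, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a deposited FPKM of at least 1 in at least 4 libraries, the same with no filter, only the groups compared, the replicate number as a block, and each library left out in turn. The labels do not say what a replicate number shares. By the data the numbers may pair the libraries in 2 comparisons. There all 4 same-number pairs correlated over 0.1 in their deviations from the group means: KO against WT at day 10 (0.141 to 0.306) and day 10 against day 5 in WT (0.105 to 0.361). In the other 7 comparisons of 2 groups at least 2 of 4 pairs did not. This was read per comparison only after the calls had been seen, and whether such correlations arise by chance was not tested. The block is 1 effect per replicate number, shared by all 6 groups, and not a pairing within a comparison. For lists the other settings were an estimated correlation, fry and a prior count of 0.5, and for the UUO signature 500 genes in place of 200. Fry tests a list by itself and not against other genes. Leaving out WT day 10 replicates 2 and 3 together, and an estimated correlation in that fit and in the one with the block, were added after seeing the data. In R 4.3.3 the steps were tested on simulated counts (15004 genes tested by edgeR) with 200 changed. For KO against WT at day 10, edgeR recovered 10.4% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 84.8% of those changed 4-fold, with 6 false calls, and for the day 10 interaction 0%, 22.4% and 65.2%, with 2. The simulated counts were drawn independently per gene from 1 mean over all 24 libraries, with no effect of UUO and no libraries set apart. In the real data WT day 10 replicates 2 and 3 lay apart, so these shares and false calls need not hold there. Gene neighbours and chromosomes come from a RefSeq table of GRCm38.p6, used for names and order only.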

Results

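RNA was measured in mouse kidney by stranded mRNA sequencing in 24 libraries. The libraries fell into 6 groups of 4, wild type (WT) and libraries labelled Pld4 knockout (KO) at day 0 (control) and at day 5 and day 10 of unilateral ureteral obstruction (UUO), a surgical model of kidney fibrosis. Total counts per library ran from 9800888 (KO day 0 replicate 2) to 22542866 (WT day 5 replicate 4). Fold changes are log2 values, each ± its SE, between groups of 4 libraries, and adjusted p values come from edgeR's quasi-likelihood test over 15080 genes unless a list is named. Genes described as higher, lower, risen or fallen had an adjusted p under 0.05. A value for a list is camera's adjusted p over the 30 lists tested. A count of list members is of those past the threshold over all genes, and the number in parentheses after it is adjusted over the list alone. The first principal component, with 65.6% of the variance, separated day 0 from obstruction, and WT day 10 replicates 2 and 3 lay apart from all other libraries on the second, with 9.45%.

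**Figure D1:**
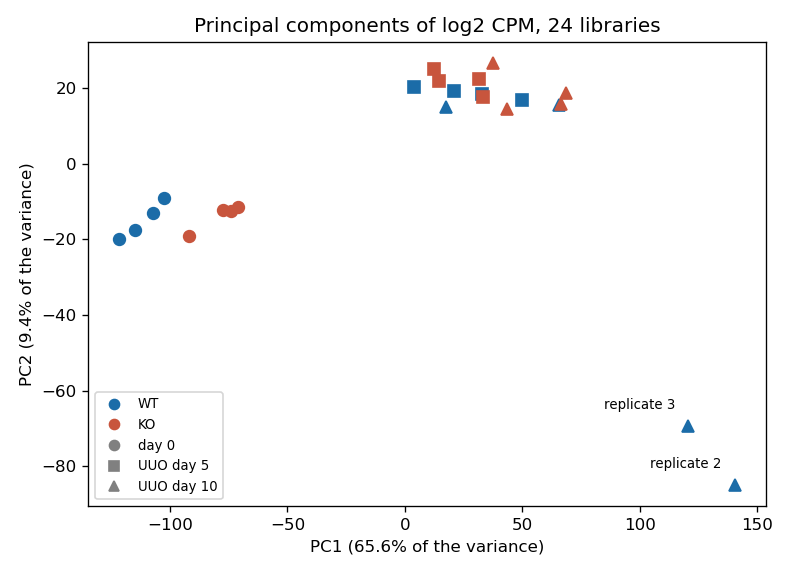
Principal components of log2 CPM over the 15080 tested genes; each point is 1 library, colour gives the genotype label and shape the day. WT UUO day 10 replicates 2 and 3 sit at -84.97 and -69.33 on the second component, and every other library lies above -20.

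The first comparison checks the labels with the targeted gene. Pld4, a transmembrane member of the phospholipase D family with 5' exonuclease activity on nucleic acids, was present in all 24 libraries. At day 0 its mean was 6.69 CPM ± 1.61 (SD, n = 4) in WT and 9.48 ± 2.48 in KO, a difference of 0.50 ± 0.29 (adjusted p = 0.438). At day 5 of UUO it was 48.3 CPM ± 1.84 in WT and 20.3 ± 8.48 in KO, -1.25 ± 0.27 (adjusted p = 0.0724), and the 2 groups did not overlap. At day 10 it was 81.5 CPM ± 27.1 in WT and 37.3 ± 10.7 in KO, a difference of -1.13 ± 0.27 (adjusted p = 0.0331, and 0.0911 at -1.11 with a term for the replicate number). Obstruction raised Pld4 in both genotypes, by 2.85 ± 0.29 at day 5 and 3.60 ± 0.30 at day 10 in WT (adjusted p = 4.65e-09 at day 10), and by 1.10 ± 0.28 and 1.98 ± 0.28 in KO (adjusted p = 1.03e-05 at day 10). The rise was smaller in KO at day 5 (interaction -1.75 ± 0.39, adjusted p = 0.0439) and at day 10 (interaction -1.63 ± 0.39, adjusted p = 0.023). The transcript was present in every library labelled KO, and at day 0 it gave no check of the labels. The deleted part of the gene is not stated, so counts over the whole gene cannot show whether the protein is lost. The day 10 call was lost without WT day 10 replicate 2 (-1.11) or 3 (-0.90), without both (-0.74) and without any 1 of the 4 KO day 10 libraries (-0.97, -1.12, -1.15 and -1.31). The day 5 difference passed with DESeq2 (-1.25) and without WT day 5 replicate 4 (-1.29) or KO day 5 replicate 1 (-1.60).

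**Figure D2:**
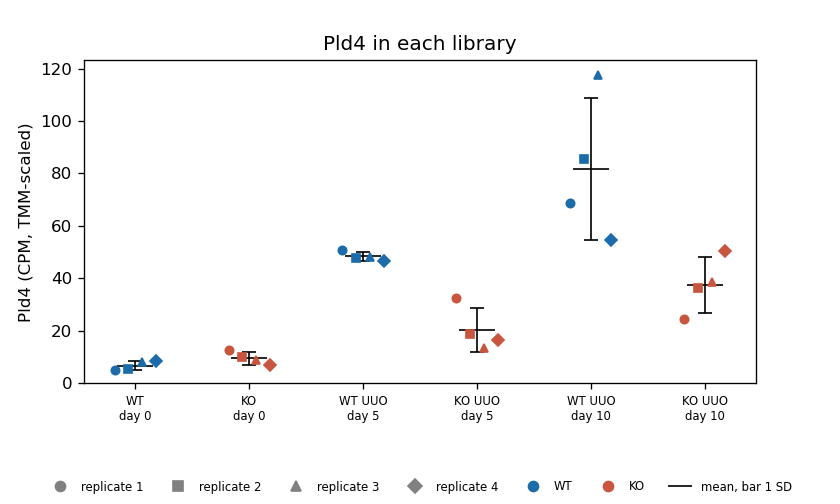
Pld4 in CPM for each of the 24 libraries, grouped by genotype label and day; points are libraries, horizontal bars group means and whiskers 1 SD. The KO libraries lie between 13.4 and 32.6 CPM at day 5 and between 24.3 and 50.3 at day 10, and the WT libraries between 46.6 and 50.9 and between 54.6 and 117.5.

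The second comparison asks how 5 days of obstruction changed the WT kidney. Genes of tubular injury rose, 16 of 18 of that list (16 adjusted over the list alone). Havcr1, a tubule membrane protein shed after injury, rose by 7.02 ± 0.32, Krt20 by 8.60 ± 0.47, the adhesion molecule Vcam1 by 5.45 ± 0.28 and the transcription factor Sox9 by 4.91 ± 0.35. Matrix genes rose as a group, with 16 of 17 collagens, 22 of 22 other matrix genes, 14 of 17 fibroblast genes and 14 of 17 metalloproteinases (17, 22, 14 and 14 adjusted over the list alone). Col1a1 rose by 3.67 ± 0.46, Col3a1 by 3.79 ± 0.49, fibronectin (Fn1) by 3.18 ± 0.41, and Acta2, the smooth muscle actin of myofibroblasts, by 1.11 ± 0.37. Tgfb1 rose by 2.07 ± 0.21 and the gelatinase Mmp2 by 3.54 ± 0.25. Leukocyte genes rose too: 19 of 20 macrophage, 13 of 14 dendritic cell, 14 of 15 T cell and 15 of 18 complement genes (19, 14, 15 and 15 adjusted over the list alone). Among them were Cx3cr1 (3.13 ± 0.20), Ccr2 (3.69 ± 0.26), Cd4 (3.54 ± 0.58) and C3 (6.83 ± 0.52).

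Genes of the working tubule fell. Of the proximal tubule list 13 of 20 fell (15 adjusted over the list alone), among them the endocytic receptor Lrp2 (-2.14 ± 0.53) and Ggt1 (-2.08 ± 0.51). Of fatty acid oxidation 14 of 17 fell (14), among them Acadl (-0.87 ± 0.16). Of the loop, distal tubule and collecting duct list 11 of 16 fell and 1 rose (11 and 1 adjusted over the list alone), with Trpm6 lower (-1.19 ± 0.20) and Kng1 higher (2.83 ± 0.26). The genes that fell furthest by the naming rule were Pvalb, a calcium-binding protein of the distal convoluted tubule (-7.89 ± 0.81), Nccrp1 (-4.47 ± 0.77), Perm1 (-4.37 ± 0.41) and Egf (-4.06 ± 0.95). Among the genes that rose furthest, 3 had no count in any WT day 0 library: the chemokines Cxcl5 and Ccl7 were at least 61.9-fold and 53.6-fold higher and Defb36 at least 40.3-fold, against a floor of 3 counts over the group.

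In all, 8536 genes passed, 4673 higher and 3863 lower. The tubular injury list passed (adjusted p = 1.05e-10; adjusted p = 0.0141 with an estimated correlation). Also past the threshold were collagens, other extracellular matrix, myofibroblast and fibroblast, TGF-beta pathway (13 of 16 rose, 14 adjusted over the list alone), metalloproteinases and the TIMPs and plasminogen system (6 of 8 rose and 1 fell, 6 and 1), at 1.23e-10 to 0.0115 (adjusted p = 0.127 to 0.249 with an estimated correlation). Macrophage, dendritic cell, complement, chemokines and inflammatory cytokines (14 of 23 rose, 14), interferon response (18 of 20, 18), endosomal nucleic acid sensing (12 of 16, 12), T cell, NK and cytotoxic (8 of 10, 9), Th1 (5 of 12, 5), Th2 (9 of 12, 9) and B and plasma cell (5 of 11, 5) rose at 9.82e-11 to 0.0441 (adjusted p = 0.127 to 0.402 with an estimated correlation). Cell cycle genes rose (16 of 16, 16; adjusted p = 1.97e-06), as did the serpins and other protease inhibitors on balance (11 of 22 rose and 3 fell, 11 and 3; adjusted p = 0.0208), with adjusted p = 0.254 to 0.29 with an estimated correlation. Proximal tubule, loop and fatty acid oxidation lists fell at 1.03e-05 to 0.00105 (adjusted p = 0.329 to 0.422 with an estimated correlation). Not past the threshold were cathepsins (adjusted p = 0.306), neutrophil (0.132), podocyte (0.228), endothelium (0.0689), urothelium (0.55), the phospholipase D family (0.328) and the genes neighbouring Pld4 (0.26). Camera sets a list against all other genes, so these lists need not be unchanged. The neutrophil score went from -1.64 ± 0.25 (SD, n = 4) to 0.574 ± 0.37, and fry, which tests a list by itself, called 29 of 30 lists. On log2(FPKM + 1) 90.2% of the called genes were higher against 54.7% here, and that scale puts the median gene 0.49 higher.

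The third comparison asks the same of day 10 in WT. The matrix and injury genes were again higher: Col1a1 by 5.12 ± 0.50, Col3a1 by 5.00 ± 0.51, Fn1 by 4.37 ± 0.43, Acta2 by 1.61 ± 0.37, Tgfb1 by 2.80 ± 0.21 and Havcr1 by 7.32 ± 0.33. In the lists 17 of 17 collagens, 21 of 22 other matrix genes, 16 of 17 fibroblast genes and 17 of 18 injury genes were up (17, 21, 16 and 17 adjusted over the list alone). Of the neutrophil list 8 of 8 rose (8), among them S100a9, a subunit of calprotectin (11.27 ± 1.68), and Csf3r (7.70 ± 0.94). The neutrophil receptor Cxcr2 was higher at a ratio of 1520 (95% counting interval 421 to 12554) and Prtn3 at 123 (21.8 to 4873), since WT day 0 held 2 and 1 counts. Arg1, arginase 1, was at 2 counts over WT day 0 and higher at a ratio of 10801 (2990 to 89190). Cxcl5, Irg1 and Fpr1, at no count there, were at least 4213-fold, 3129-fold and 823-fold higher. These ratios and bounds pool the 4 libraries and hold no spread between them. In WT day 10 replicates 2 and 3 Cxcr2 stood at 135 and 140 CPM and S100a8 at 991 and 2141, against at most 1.27 and 3.83 in any other library. The pooled ratio of Cxcr2 thus does not describe WT day 10 replicates 1 and 4, at 1.09 and 1.27 CPM.

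Macrophage genes rose (20 of 20, 20 adjusted over the list alone), with C1qa at 4.46 ± 0.30. So did chemokines and cytokines (22 of 23, 22), with Ccl2, which attracts monocytes, at 7.26 ± 0.49, and T cell genes (15 of 15, 15), with Cd4 at 4.46 ± 0.58. All of the proximal tubule (20 of 20) and fatty acid oxidation (17 of 17) genes fell (20 and 17 adjusted over the list alone), with Lrp2 at -2.89 ± 0.55 and Acadvl at -1.80 ± 0.24. The genes that fell furthest were Pvalb (-8.89 ± 0.87), Hrg (-5.40 ± 0.99), Nccrp1 (-5.29 ± 0.81) and Ces1g (-4.95 ± 0.69). In all, 10267 genes passed, 5700 higher and 4567 lower. Of 30 lists 22 passed, 19 up and 3 down, of which tubular injury also held with an estimated correlation (adjusted p = 0.0467). The named lists stood at 6.51e-11 to 0.00282 (adjusted p = 0.157 to 0.298 with an estimated correlation). Without WT day 10 replicates 2 and 3, left out after the data were seen, 8628 genes passed and 8133 of the 8136 shared ones kept their direction. On log2(FPKM + 1) 80.2% were higher against 55.5% here.

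The fourth comparison asks how 5 days of obstruction changed the KO kidney. Havcr1 rose by 7.75 ± 0.33, Krt20 by 5.94 ± 0.41 and Vcam1 by 3.78 ± 0.26, and 16 of 18 injury genes rose (16 adjusted over the list alone). Matrix genes rose, with 16 of 17 collagens, 22 of 22 other matrix genes, 15 of 17 fibroblast genes and 14 of 17 metalloproteinases (17, 22, 16 and 14). Among them were Col1a1 (3.86 ± 0.47), Col3a1 (3.93 ± 0.49), Fn1 (3.20 ± 0.41), Acta2 (1.90 ± 0.37), Tgfb1 (1.90 ± 0.21) and Mmp2 (3.36 ± 0.24). The metalloproteinase Mmp7, at 1 count over KO day 0, was higher at a ratio of 735 (132 to 29055), Sprr2f at 633 (113 to 25027), and Il1f6, at no count there, at least 116-fold. Macrophage (18 of 20, 19) and complement genes (14 of 18, 14) rose, with Cx3cr1 at 1.94 ± 0.19 and C3 at 4.91 ± 0.47. So did the cell cycle genes (16 of 16, 16), with Mcm5 at 2.09 ± 0.20. None of the 15 T cell genes passed, over all genes or adjusted over the list alone (Lck 0.62 ± 0.42, adjusted p = 0.245). Of the interferon genes 3 of 20 did (1), Ddx58 (0.75 ± 0.18), Irf9 (0.50 ± 0.17) and Ifi27l2a (1.20 ± 0.42).

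The genes that fell furthest were Pvalb (-5.86 ± 0.68), the transporter Slc22a29 (-4.58 ± 1.00), Hpd (-4.33 ± 1.11) and Cyp2d12 (-4.25 ± 1.08). Lower were 6 of 20 proximal tubule genes (5 adjusted over the list alone) and 14 of 17 of fatty acid oxidation (16). In all, 5951 genes passed, 3381 higher and 2570 lower, and 18 of 30 lists, 15 up and 3 down. Tubular injury held with an estimated correlation (adjusted p = 0.00371), and the other lists named as moving stood at 4.98e-13 to 6.81e-04 (adjusted p = 0.11 to 0.541 with an estimated correlation). The T cell and interferon lists missed the threshold (adjusted p = 0.848 and 0.912). On log2(FPKM + 1) 95.5% of called genes were higher against 56.8% here, and without a filter on that scale 9277 genes passed.

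The fifth comparison asks the same of day 10 in KO. Col1a1 rose by 4.37 ± 0.48, Col3a1 by 4.05 ± 0.49, Fn1 by 3.69 ± 0.41, Acta2 by 1.68 ± 0.37, Tgfb1 by 2.11 ± 0.21 and Havcr1 by 7.49 ± 0.33. In the lists 17 of 17 collagens, 22 of 22 other matrix genes, 16 of 17 fibroblast genes and 16 of 18 injury genes were up (17, 22, 16 and 16 adjusted over the list alone). Mmp7 was higher at a ratio of 2062 (370 to 81452), and Il1f6 and the surfactant protein Sftpd at least 188-fold and 57.7-fold. Macrophage (19 of 20, 19), dendritic cell (11 of 14, 13) and T cell genes (8 of 15, 9) rose, with Cx3cr1 at 2.35 ± 0.19, Cd83 at 2.37 ± 0.30 and Cd4 at 1.36 ± 0.47. Of the neutrophil genes 2 of 8 passed (1), and that list did not (adjusted p = 0.208). Proximal tubule (18 of 20, 19) and fatty acid oxidation genes (17 of 17, 17) fell, with Lrp2 at -2.37 ± 0.54 and Acaa2 at -1.81 ± 0.29. So did Pvalb (-8.64 ± 0.85), Slc22a29 (-5.38 ± 1.06), Perm1 (-5.04 ± 0.44) and Calb1 (-3.98 ± 0.62). In all, 8193 genes passed, 4268 higher and 3925 lower, and 20 of 30 lists, 17 up and 3 down. Tubular injury held with an estimated correlation (adjusted p = 0.0146), and the others named as moving stood at 1.59e-10 to 0.0208 (adjusted p = 0.166 to 0.558 with an estimated correlation). On log2(FPKM + 1) 88.1% of called genes were higher against 52.1% here.

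The sixth comparison sets day 10 against day 5 within each genotype. In WT, 20 of 20 macrophage genes (20 adjusted over the list alone), 7 of 8 neutrophil genes (7), 15 of 23 chemokines and cytokines (19) and 10 of 17 metalloproteinases (12) were higher at day 10. Examples were Arg1 (10.70 ± 1.74), Irg1 (9.52 ± 1.74), the neutrophil chemokine Cxcl3 (9.12 ± 1.43), Ltf (8.52 ± 1.45), Mmp8 (7.94 ± 1.33), Mmp3 (3.67 ± 0.59) and Ccl3 (6.42 ± 1.13). Col1a1 was higher by 1.45 ± 0.42 (adjusted p = 0.0338), Fn1 by 1.19 ± 0.38 (0.0458) and Tgfb1 by 0.73 ± 0.20 (0.0239). Col3a1 stood at 1.21 ± 0.44 (0.0796). Same-number libraries of these 2 groups correlated in their deviations. With a term for the replicate number, shared by all 6 groups, Col1a1 stood at 1.35 (adjusted p = 0.0543). The list of other matrix genes then passed as higher (0.0386, and 0.597 with an estimated correlation), and 8 of 17 fatty acid oxidation genes were lower. Gsta2 (-2.21 ± 0.61), Apoc3 (-2.11 ± 0.56) and Cpb2 (-1.70 ± 0.48) were lower, with 3 of 17 fatty acid oxidation genes (7 adjusted over the list alone). In all, 1628 genes passed, 1186 higher and 442 lower, and 17 lists, 13 up and 4 down. Those named stood at 1.12e-10 to 1.51e-05 (adjusted p = 0.333 with an estimated correlation). The call rests on WT day 10 replicates 2 and 3: without both, edgeR called 0 genes (845 at an unadjusted p under 0.05), and without either alone 439 and 359. In a fit of the 2 groups alone it called 0 (1863 at an unadjusted p under 0.05), against 2252 with DESeq2 and 1462 with limma on log2(FPKM + 1). Other single libraries moved it to 2699 and 4515 (WT day 10 replicates 1 and 4) and to 819, 729 and 915 (WT day 5 replicates 1 to 3).

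In KO, 3 genes passed, all higher at day 10: Ccr7, a chemokine receptor of migrating dendritic cells (1.98 ± 0.29), Il12b, a subunit of interleukin 12 (2.83 ± 0.43), and Calcr, the calcitonin receptor (2.48 ± 0.35), which is named after its value was seen. Col1a1 stood at 0.51 ± 0.42 (adjusted p = 0.625) and Tgfb1 at 0.21 ± 0.20 (0.664). Of the lists, 17 passed, 14 up and 3 down. Among them were the interferon response (adjusted p = 1.74e-12; no gene passed, 14 of 20 adjusted over the list alone), T cell (1.27e-06; none passed in either way) and dendritic cell (1.27e-06; 1 passed, 2 adjusted over the list alone), with adjusted p = 0.365 to 0.413 with an estimated correlation. The interferon response did not pass in this contrast of WT (adjusted p = 0.599), and the difference was not tested. Leaving out 1 library gave 0 (KO day 5 replicate 4), 5 (KO day 5 replicate 3) or 12 genes (KO day 10 replicate 4). Leaving out WT day 10 replicates 2 and 3, which enter the shared spread, gave 54, and DESeq2 70.

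The seventh comparison sets KO against WT at day 0, in control kidneys. Immune genes were higher in KO: 18 of 20 interferon response genes (20 adjusted over the list alone), 12 of 15 T cell (15), 6 of 10 NK and cytotoxic (8), 8 of 14 dendritic cell (10), 12 of 20 macrophage (16), 6 of 12 Th1 (10) and 10 of 18 complement genes (11). Examples were Irf7 (2.37 ± 0.38), Usp18 (2.03 ± 0.30) and Ifit1 (2.46 ± 0.40) of the interferon response, and Cd4 (2.99 ± 0.59) and Cd8b1 (4.28 ± 0.59) of T cells. Others were Nkg7 of cytotoxic granules (4.46 ± 0.64), the antigen presentation genes Cd74 (2.72 ± 0.34) and H2-Ab1 (2.34 ± 0.36), Cx3cr1 (1.80 ± 0.20), Il12b (3.72 ± 0.53) and C1qa (1.60 ± 0.27). The chemokine Ccl7, with no count in WT, was at least 10.7-fold higher, and Ccl2 was higher by 3.01 ± 0.53. Of the Serpina1 genes, which encode alpha-1-antitrypsins, 4 were lower in KO: Serpina1d (-8.07 ± 1.21; 249 CPM ± 27.4 (SD, n = 4) in WT and 0.986 ± 0.666 in KO), Serpina1a (-7.12 ± 1.08) and Serpina1b (-1.77 ± 0.38). Serpina1c, at 2 counts over KO, was lower at a ratio of 72.8 (19.8 to 607). Serpina1e, at 2 counts over WT, was higher in the counts at a ratio of 12 (2.99 to 105; adjusted p = 0.0272) and lower on log2(FPKM + 1), at -2.83. Serpina6, the corticosteroid-binding globulin, was higher at a ratio of 244 (43.3 to 9665). The Serpina1 genes are near-identical copies, so their single values are uncertain.

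Other genes that were higher by the naming rule were Pydc3 (5.68 ± 0.52), Cyp26b1, which breaks down retinoic acid (3.86 ± 0.92), the prolactin receptor Prlr (4.39 ± 0.85) and the transporter Slc7a12 (5.58 ± 1.05). Wdfy1 (-1.53 ± 0.22), Bcat1 (-1.86 ± 0.53), Kif20b (-1.60 ± 0.46), Pcdh7 (-1.53 ± 0.33) and Hsd17b11 (-1.41 ± 0.29) were lower. Prlr and Slc7a12 stood at 427 and 440 CPM in KO day 0 replicate 4 and at 78.2 or less and 67.7 or less in the other 3 KO libraries. Those 3 still lay above every WT day 0 library, at 25.7 and 13.9 or more against 9.24 and 4.93 or less. KO day 0 replicate 4 had Xist at 879 CPM and Ddx3y at 0.390, where every other library of the series had at most 0.692 and at least 58.0. Its Eif2s3y and Kdm5d stood at 0.234 and 0 CPM. By these sex-linked genes it came from a female and all other libraries from males. The sizes for Prlr and Slc7a12 thus cannot be put down to genotype alone. Of the matrix genes, 3 of 17 collagens (5 adjusted over the list alone) and 5 of 22 others (6) were higher, such as Bgn (1.00 ± 0.20) and Col15a1 (0.90 ± 0.21), and both lists passed (0.00163 and 8.12e-04; adjusted p = 0.416 with an estimated correlation). Col1a1 stood at 0.17 ± 0.42 (adjusted p = 0.901) and Tgfb1 at 0.35 ± 0.21 (0.467). In all, 630 genes passed, 550 higher and 80 lower. Of 30 lists 18 passed, with cell cycle the one lower (no gene passed, 3 of 16 lower adjusted over the list alone, adjusted p = 0.002; adjusted p = 0.503 with an estimated correlation). With an estimated correlation 6 lists held, NK and cytotoxic (adjusted p = 0.0273), dendritic cell (0.0238), interferon response (0.0363), T cell (0.0413), complement (0.0432) and Th1 (0.0484). Macrophage (0.0677) did not. Leaving out WT replicate 1, 2 or 4 or KO replicate 4 gave 296, 414, 417 and 371 genes. A fit of the 2 groups alone gave 1507, and one without WT day 10 replicates 2 and 3, which enter the shared spread, 1274.

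The eighth comparison sets KO against WT at day 5 of UUO. Few genes passed the threshold: Pydc3 (2.89 ± 0.39), Igj, the joining chain of IgA and IgM (2.84 ± 0.54), Prox1, a transcription factor of lymphatic endothelium (1.75 ± 0.35), Slc35g1 (1.05 ± 0.20) and Adss (0.50 ± 0.09) were higher in KO. Serpina1a (-5.97 ± 0.94), Serpina1d (-5.31 ± 1.06), Zbtb16 (-3.38 ± 0.55), Hif3a (-2.79 ± 0.52), Wdfy1 (-2.22 ± 0.22), the macrophage elastase Mmp12 (-2.21 ± 0.40), Cyp27b1, which activates vitamin D (-1.75 ± 0.35), and Sult1a1 (-1.51 ± 0.24) were lower. Serpina1e was higher by 4.07 ± 0.66 in the counts and lower on log2(FPKM + 1), at -0.65. The fibrosis genes did not pass: Col1a1 0.36 ± 0.42 (adjusted p = 0.711), Col3a1 0.41 ± 0.43 (0.683), Fn1 0.09 ± 0.37 (0.935), Acta2 0.32 ± 0.36 (0.697) and Tgfb1 0.17 ± 0.20 (0.705). In all, 22 genes passed, 10 higher and 12 lower. At an unadjusted p under 0.05 there were 2104, against 2347 for KO against WT at day 0 and 2216 at day 10. Of the lists 2 passed: T cell (adjusted p = 0.0227) and Th1 (0.0234), were higher with no gene past the threshold in either way (adjusted p = 0.987 for each with an estimated correlation). Leaving out WT day 5 replicate 4 gave 1935 genes and KO day 5 replicate 1 gave 477, and other single libraries (WT replicates 1 to 3, KO replicates 2 and 3) 9 to 13. Leaving out WT day 10 replicates 2 and 3 gave 116. DESeq2 called 80 and log2(FPKM + 1) 49. WT day 5 replicates 1 to 3 and KO day 5 replicate 1 had the nuclear RNA Malat1 at 1193 to 2290 CPM and the other 4 day 5 libraries at 253 to 324. Neat1 (1162 to 2322 against 368 to 524) and Ccnl2 (156 to 288 against 53.0 to 56.8) parted these libraries in the same way, as did Clk1, Clk4 and Ccnl1. The cause was not tested.

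The ninth comparison sets KO against WT at day 10 of UUO. Genes of the neutrophil, metalloproteinase, macrophage and chemokine lists were lower in KO: 7 of 8 neutrophil genes (7 adjusted over the list alone), 6 of 17 metalloproteinases (11), 6 of 20 macrophage genes (11) and 5 of 23 chemokines and cytokines (13). Examples were S100a9 (-9.56 ± 1.52), S100a8 (-9.46 ± 1.52), Arg1 (-9.44 ± 1.60), the lectins Clec4d (-8.48 ± 1.34) and Clec4e (-8.22 ± 1.38), Cxcl3 (-8.17 ± 1.34), Cxcr2 (-7.52 ± 1.19), the neutrophil collagenase Mmp8 (-7.79 ± 1.31), Mmp12 (-2.52 ± 0.38) and Timp1 (-3.54 ± 0.78). Without WT day 10 replicates 2 and 3, Mmp12 passed (-1.77) and the other 9 of these genes did not (-1.72 to -0.23). In those libraries the neutrophil list scores were 7.70 and 7.98 against 1.20 and 1.07 in WT replicates 1 and 4 and 0.258 to 0.723 in KO. Their proximal tubule scores were 3.61 and 5.51 against 7.75 and 9.57. Higher in KO were Pydc3 (3.49 ± 0.39), Apol9a (2.90 ± 0.48), Igj (2.60 ± 0.53), the T cell genes Cd8a (1.83 ± 0.38), Cd8b1 (1.80 ± 0.43) and Tox (1.49 ± 0.31), and H2-Q2 (1.29 ± 0.28). Il12b was higher by 2.19 ± 0.40. Elane, the neutrophil elastase, had 3, 12 and 1 counts in WT replicates 2 and 3 and KO replicate 2 and none elsewhere, too few to be tested.

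The fibrosis genes did not pass: Col1a1 -0.57 ± 0.42 (adjusted p = 0.54), Col3a1 -0.69 ± 0.44 (0.473), Fn1 -0.60 ± 0.37 (0.464), Acta2 -0.39 ± 0.36 (0.624) and Tgfb1 -0.34 ± 0.20 (0.437). In all, 212 genes passed, 21 higher and 191 lower. Of the lists 15 passed, 8 up and 7 down. Neutrophil (adjusted p = 2.45e-08), metalloproteinases (7.71e-05), macrophage (2.55e-06), chemokines (0.00481), Th2 (6.65e-04; 2 of 12 lower, 6 adjusted over the list alone) and 2 others were lower. Higher were interferon response (4.06e-10; no gene passed, 8 of 20 higher adjusted over the list alone), dendritic cell (7.01e-06; none and 5 of 14), proximal tubule (2.81e-07; none in either way) and 5 others. None held with an estimated correlation (adjusted p = 0.286 to 0.593 with an estimated correlation), and fry called 3 of 30 lists (lowest adjusted p = 0.0289). The T cell list was among those higher (adjusted p = 0.00336; adjusted p = 0.593 with an estimated correlation; 2 of 15 higher, 2 adjusted over the list alone), with a median of -0.05, a mean of 0.19 and a median of 0.32 on log2(FPKM + 1). Without WT replicates 2 and 3, 69 genes passed, 61 higher and 8 lower, with 16 of the 212 among them, and the macrophage (adjusted p = 0.00561), chemokine (8.27e-06), complement (2.13e-04) and endosomal sensing lists (1.32e-04) were higher in KO and proximal tubule lower (0.0108), at 0.0856 to 0.659 with an estimated correlation. In that fit Th1, interferon response, T cell and B and plasma cell were higher and held with an estimated correlation (adjusted p = 0.00259 to 0.03). Libraries of the same number correlated in their deviations in these 2 groups. With a term for that number, which is shared by all 6 groups and is no pairing of these 2 alone, 19 genes passed, 8 higher. Arg1, Clec4d, Clec4e, Cxcl3, Timp1, Igj, Cd8a, Cd8b1 and Tox then stood at adjusted p = 0.0503 to 0.118. With that term 4 neutrophil genes and 2 metalloproteinases passed as lower and no macrophage, chemokine, Th2 or T cell gene passed, and no list changed its call (none held with an estimated correlation). A fit of the 2 groups alone called 0 genes (1043 at an unadjusted p under 0.05), DESeq2 505 and log2(FPKM + 1) 41, with 87.8% higher. Single libraries moved the count to 1101, 48 and 2045 (WT replicates 1, 2 and 4) and to 23, 31, 33 and 26 (KO replicates 1 to 4).

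The tenth comparison tests whether the day 5 response to obstruction differed between the genotypes. Immune genes responded less in KO: 6 of 20 interferon response genes passed as lower (17 adjusted over the list alone), 3 of 14 dendritic cell (9), 2 of 10 NK and cytotoxic (7) and 1 of 15 T cell genes (9). Examples were Mx1 (-4.26 ± 0.86), Irf7 (-2.57 ± 0.52) and Mx2 (-2.80 ± 0.56) of the interferon response, with Ccr7 (-3.10 ± 0.46), Itgax (-2.48 ± 0.39), Nkg7 (-3.62 ± 0.81), Cd8b1 (-3.25 ± 0.74) and the chemokine Ccl2 (-3.51 ± 0.63). Zbtb16 (-4.17 ± 0.73), Slc10a6 (-3.60 ± 0.71) and Phf11a (-3.50 ± 0.66) were lower too, and Prox1 (adjusted p = 0.0361) and Prkar2b (1.56 ± 0.27) higher. The interferon, T cell, NK and dendritic cell lists were already higher in KO at day 0, as given above, and the contrast subtracts that level. Col1a1 stood at 0.19 ± 0.59 (adjusted p = 0.903) and Tgfb1 at -0.17 ± 0.29 (0.806). In all, 85 genes passed, 5 higher and 80 lower, and 14 lists, 13 down and 1 up. Interferon response (adjusted p = 4.52e-18), dendritic cell (9.72e-11), T cell (2.46e-09) and NK and cytotoxic (1.05e-07) led, and none held with an estimated correlation (adjusted p = 0.0582 to 0.308 with an estimated correlation). Fry, which tests a list by itself, called 6 of 30 lists (lowest adjusted p = 4.97e-04). Single libraries moved the count to between 27 (WT day 0 replicate 1) and 884 (WT day 5 replicate 4), with 244 without KO day 5 replicate 1, 37 to 56 without 11 further ones and 31 without KO day 5 replicate 2. It was 645 without WT day 10 replicates 2 and 3, 263 with DESeq2 and 510 in a fit of the 4 groups alone. The difference in Malat1 among the day 5 libraries, given above, runs across the day 5 groups of this contrast too.

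The eleventh comparison tests the same for day 10. Macrophage genes rose less in KO (18 of 20 passed as lower, 20 adjusted over the list alone), among them C1qa (-2.18 ± 0.38), C1qc (-2.24 ± 0.40) and Ccr2 (-1.90 ± 0.34). So did chemokines and cytokines (8 of 23, 14), with Ccl2 (-3.72 ± 0.62) and Ccl3 (-8.47 ± 1.96), and complement genes (8 of 18, 10), with C3ar1 (-2.89 ± 0.51). Lower too were sensors of endosomal nucleic acids (6 of 16, 10), with Tlr7 (-2.65 ± 0.43) and Tlr13 (-3.75 ± 0.76). These 4 lists passed as higher in KO at day 0 (with an estimated correlation 0.0432 for complement and 0.0677 to 0.195 for the others), and the contrast subtracts that level. Their scores at day 0 were 2.12 in WT and 3.69 in KO (macrophage), 0.298 and 1.72 (chemokines), 3.05 and 3.98 (complement) and 2.96 and 3.97 (endosomal sensing). Without WT day 10 replicates 2 and 3 these lists turned to higher in KO at day 10, as given above, and passed as lower in this contrast (adjusted p = 2.50e-30 to 1.55e-05; 0.00647 to 0.0521 with an estimated correlation). Further down were Hdc, which makes histamine (-12.36 ± 2.38), S100a9 (-9.71 ± 2.52), Slfn4 (-9.13 ± 1.86), Mmp9 (-7.83 ± 1.91) and Tgfbi (-3.46 ± 0.67). Higher were Tgm7 (1.52 ± 0.41), Hsd17b11 (1.48 ± 0.40) and Zfp810 (1.24 ± 0.30). Among protease inhibitors, Serpina10 (-3.38 ± 0.49) and Serpina3g (-4.26 ± 0.84) were lower. Col1a1 stood at -0.74 ± 0.59 (adjusted p = 0.583), Col3a1 at -0.95 ± 0.62 (0.489), Fn1 at -0.68 ± 0.53 (0.576), Acta2 at 0.07 ± 0.51 (0.964) and Tgfb1 at -0.69 ± 0.29 (0.241). In all, 490 genes passed, 20 higher and 470 lower, and 21 lists, 18 down and 3 up. Macrophage (adjusted p = 4.07e-23), chemokines (9.20e-09), complement (3.00e-07) and endosomal sensing (8.75e-08) were among them, and none held with an estimated correlation (adjusted p = 0.215 with an estimated correlation). Fry, which tests a list by itself, called 14 of 30 lists (lowest adjusted p = 0.0026). Without WT day 10 replicates 2 and 3, 153 genes passed, 149 lower, with 141 of the 490 among them. A fit of the 4 groups alone called 2, log2(FPKM + 1) 1 and DESeq2 850. Single libraries moved the count to 246 and 312 (WT day 0 replicates 1 and 4), 320 and 324 (KO day 0 replicates 1 and 2), 997 and 1808 (WT day 10 replicates 1 and 4) and 281 (KO day 10 replicate 1).

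The last comparison asks whether the obstruction response as a whole was lower or higher in KO. The 200 genes that rose and the 200 that fell with the lowest p at 1 UUO day in WT were tested between the genotypes at the other UUO day. At day 5 neither the genes that had risen by day 10 nor those that had fallen passed (adjusted p = 0.652 for each). At day 10 neither set from day 5 passed (0.795 for each). With an estimated correlation the adjusted p values were 0.925 at day 5 and 0.955 at day 10. Without WT day 10 replicates 2 and 3 the genes that rose were higher in KO at day 10 (adjusted p = 4.86e-15) and those that fell lower (8.95e-08), and the genes that rose were higher at day 5 (0.0307). With an estimated correlation these stood at 0.15, 0.349 and 0.896. With a term for the replicate number those that fell were higher at day 10 (adjusted p = 0.0298; 0.822 with an estimated correlation). Single libraries also moved these tests. At day 5 the genes that fell were lower without WT day 5 replicate 3 (adjusted p = 0.0493) or KO day 5 replicate 2 (4.02e-05) and higher without WT day 5 replicate 4 (0.0239). At day 10 the genes that rose were higher without WT day 10 replicate 2 (0.00856) or KO day 10 replicate 4 (0.0453) and lower without WT day 10 replicate 4 (2.21e-06). Those that fell were lower without KO day 10 replicate 4 (0.0453) and higher without WT day 5 replicate 4 (0.0272) or WT day 10 replicate 4 (5.69e-13).

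**Figure D3:**
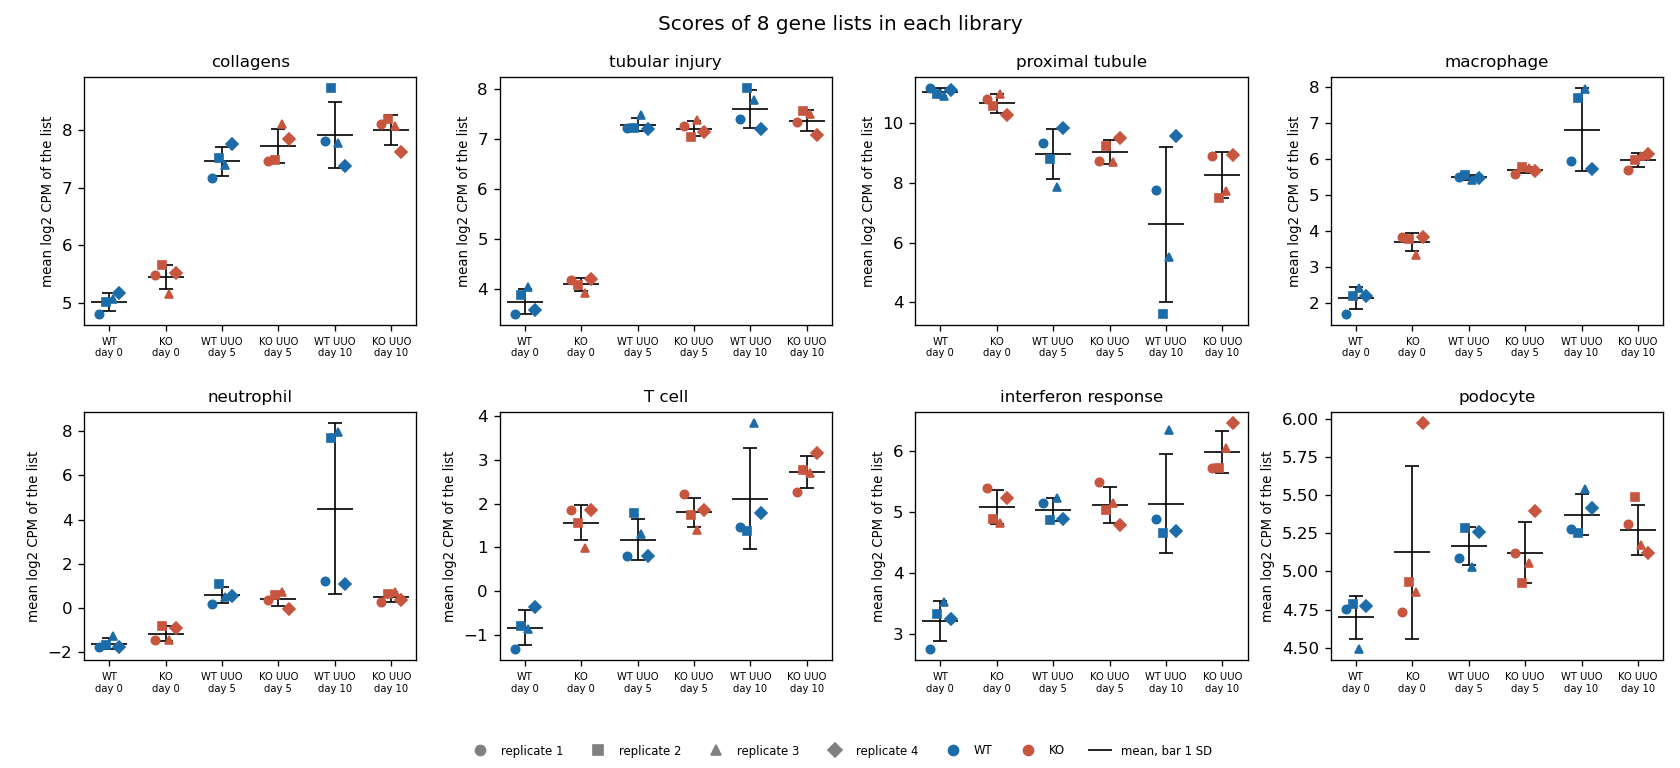
Mean log2 CPM of the tested members of 8 gene lists in each of the 24 libraries; points are libraries, horizontal bars group means, whiskers 1 SD, and axes differ between panels. WT UUO day 10 replicates 2 and 3 reach 7.70 and 7.98 on the neutrophil list, where all other libraries lie at or below 1.20.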

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

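The tests of explanations and the counts of other splits in this part were all set up after the results had been seen. A library was listed here where its gap to the nearest other library of its group was large against the range of the 4, which chance gives in about 1 in 20 groups; 18 of 246 groups did.

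WT day 10 replicates 2 and 3 lay apart from all other libraries, with S100a8 at 991 and 2141 CPM and neutrophil scores of 7.70 and 7.98. A swap with KO libraries is argued against, since both lay on the WT side at 6 of 8 genes called at day 0 and at day 5 (not at Serpina1a and Serpina1d) and no KO day 10 library did at any. Dilution of the kidney RNA is argued against by proximal tubule scores that fell by at least 3.35 (log2) more than podocyte scores, against 1.82 between replicates 1 and 4. Low depth is argued against for replicate 2, with 17.9 M counts against 17.4 M in replicate 1, and for replicate 3, at 15.4 M, since the 12 libraries with fewer counts had neutrophil scores of at most 1.07. No biological explanation was tested, since the labels name none within a group, and a difference in severity or an infection stays open.

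Genes called between KO and WT at all 3 days were 1700112E06Rik, Gm15446, Igj, Pydc3 and Serpina1e, higher in KO, and Serpina1a, Serpina1d and Wdfy1, lower (with a term for the replicate number Igj, Serpina1a and Serpina1d stood at adjusted p = 0.0597 to 0.136 at day 10). For reads moved between Serpina1 copies, the summed CPM of Serpina1a to Serpina1e was lower in KO by log2 -4.96, -2.70 and -1.59 at days 0, 5 and 10, with overlapping groups at day 10, so this cannot be told apart there. A region linked to Pld4 is argued against for the 5 genes on other chromosomes, and it cannot be told apart for the 3 Serpina1 genes on its chromosome, with 95 protein-coding genes or more between them and Pld4. Strain background carried along at unlinked loci cannot be told apart from an effect of Pld4 either, since the 8 genes lie on 4 chromosomes and the labels give no strain. Loss of Pld4 itself, the difference the design names, stays open and may act on some of them.

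Immune genes were higher in KO at day 0. A single library is argued against, since all 10 immune lists that were higher stayed past the threshold with each of the 8 libraries left out in turn, with 296 to 702 genes called. These list calls use the preset correlation, and with an estimated one 6 lists held in the fit of all libraries. A smaller share of tubule RNA would raise other cell types alike and is argued against: macrophage and dendritic cell scores were 1.56 and 1.45 (log2) higher in KO and endothelium and podocyte scores 0.524 and 0.423, an excess of at least 0.930 and in each case over its SD (0.395 to 0.705). The proximal tubule score was 0.384 lower and the loop, distal tubule and collecting duct score 0.153 higher. More immune cells in the tissue taken, a change within them and the genotype, which the design names, were not tested and stay open. Strain background, age and surgery batch, which the labels do not give, cannot be told apart from the genotype. Sex was not matched, since by Xist and Ddx3y KO replicate 4 was female and the other libraries male. Without that library 371 genes passed and all 10 lists stayed past the threshold.

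For KO against WT at day 0, no other split gave as many genes (630 genes, highest of the other 34 splits 1). That share, 1 of 35 or 2.86%, is the lowest that 35 splits allow. It is under 0.05 for a comparison taken alone and was not adjusted over the comparisons, so it does not exclude chance. Chance cannot be excluded at day 5 either (22 genes, highest other 4016, with 3 of 35 splits as large) or at day 10 (212, 1943, with 10 of 35). The split with 4016 sets WT day 5 replicates 1 to 3 and KO day 5 replicate 1 against the rest, and the split with 1943 sets replicates 1 and 4 of both day 10 groups against replicates 2 and 3, so both point to a structure of the samples other than genotype. With a term for the replicate number 19 genes passed at day 10. Of the 8 splits there that part all 4 same-number pairs, 3 were as large (highest other 397), and of the 27 that keep a pair together 7 (1943), so 8 splits are too few for a share under 0.05. For UUO against day 0, no other split gave as many genes, with 1 of 35 as large in each and the same limit. The counts and the highest other split were 8536 and 1398 at day 5 in WT and 10267 and 4142 at day 10 in WT. In KO they were 5951 and 2 at day 5 and 8193 and 91 at day 10. For day 10 against day 5 it cannot be excluded in WT (1628 genes, highest other 4440, 5 of 35). There 1 of the 8 splits that part all pairs (highest other 1476) and 4 of the other 27 were as large. In KO 1 of 35 splits was as large (3 genes, highest other 0), the lowest share that 35 splits allow. Without KO day 5 replicate 4 no gene passed, so chance is not excluded for so small a call. For the interactions chance cannot be excluded at day 5 (85 genes, highest other 1816, with 6 of 80 splits as large). At day 10 it was 2 of 80 splits (490 genes, highest other 2223). These splits exchange the genotype labels at day 0 too, where 630 genes differed between the genotypes. They mix that difference into the groups, so they cannot decide on chance for the day 10 interaction. The same limit holds for 80 splits that exchange the day 10 labels only within same-number pairs (490 genes, highest other 918, 2 of 80).

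The response to UUO differed between the genotypes in 85 genes at day 5 and 490 at day 10, and for Pld4 by -1.75 and -1.63 (log2). KO day 0 replicate 4 had Xist at 879 CPM (others of its group 0.601 or less) and Ddx3y at 0.390 (others 84.2 or more), with a podocyte score of 5.97. Malat1 stood at 1547 CPM in KO day 5 replicate 1 (others 253 to 324) and at 1846 in KO day 10 replicate 2 (others 447 to 522). Serpina1a stood at 59.0 CPM in WT day 0 replicate 3, and Acta2 at 408 in WT day 10 replicate 2. Scores apart from their group were Th1 (4.66) and interferon response (6.33) in WT day 10 replicate 3, complement in WT day 5 replicate 4 (5.73) and KO day 5 replicate 1 (5.43), and other extracellular matrix in KO day 10 replicate 4 (6.29). The remaining ones were macrophage in KO day 0 replicate 3 (3.33), dendritic cell in WT day 0 replicate 1 (1.39), podocyte in WT day 0 replicate 3 (4.49), fatty acid oxidation in WT day 0 replicate 2 (8.66), tubular injury in WT day 5 replicate 3 (7.48) and loop, distal tubule and collecting duct in KO day 5 replicate 3 (5.65).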

How the results depend on the processing

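The setting without WT day 10 replicates 2 and 3, and the estimated correlation in that fit and with the replicate block, were chosen after seeing the data, and the others before the data were examined. Of 410 values of main results under another setting, 265 kept their direction and their side of the threshold, or stayed within 1.5 times for a count, as did 7316 of 8414 for named genes and 5082 of 5989 for lists. KO against WT at day 0 (630 genes) gave 958 with DESeq2, 361 on log2(FPKM + 1), 304 there with no filter, 1507 with only the groups compared and 1274 without the 2 libraries. At day 5 (22) it gave 80 with DESeq2, 49, 39 and 59 on log2(FPKM + 1), log2(FPKM + 0.1) and with no filter, and 116 without the 2 libraries. At day 10 (212) it gave 505 with DESeq2, 41, 24 and 68 on FPKM, 0 with only the groups compared (edgeR, 1043 at an unadjusted p under 0.05) and 69 without the 2 libraries. UUO at day 5 in KO (5951) gave 9277 on log2(FPKM + 1) with no filter. Day 10 against day 5 gave in WT (1628) 990 on log2(FPKM + 1) with no filter, 0 with only the groups compared and 0 without the 2 libraries (edgeR, 1863 and 845 at an unadjusted p under 0.05; DESeq2 2252), and in KO (3) 70 with DESeq2, 5 and 15 on log2(FPKM + 1) with and without a filter, 9 with only the groups compared and 54 without the 2 libraries. The interaction at day 5 (85) gave 263 with DESeq2, 6 and 8 on log2(FPKM + 1) with and without a filter, 510 and 645, and at day 10 (490) 850 with DESeq2, 1, 162 and 4 on FPKM, 2 with only the groups compared and 153 without the 2 libraries. Pld4 at day 5 passed with DESeq2 (-1.25), on FPKM (-1.21, -1.31 and -1.21) and without the 2 libraries (-1.27); at day 10 it did not pass on FPKM (-1.003, -1.05 and -1.003), with only the groups compared (-1.12) or without the 2 libraries (-0.74). On FPKM the median gene shifted by 0.48 to 0.51 in the UUO comparisons. Over all groups 21 of 60 same-number pairs correlated over 0.1 (-0.36 to 0.59), and 8 of 24 libraries matched their own number best. Outside the 2 comparisons named under processing single pairs correlated too, the highest being WT and KO day 5 replicate 4 (0.591). In no other comparison of 2 groups did all 4 pairs do so. Whether libraries of a number share more than the number stays open. With the replicate block KO against WT at day 10 gave 19 genes, Pld4 at day 10 stood at -1.11 without passing, and the UUO signature gave adjusted p = 0.332 (fell, day 5) and 0.0298 (fell, day 10), and the block changed no other main result. In the 2 comparisons named under processing the block also ended the calls of Col1a1 (day 10 against day 5 in WT), Arg1, Clec4d, Clec4e, Cxcl2, Cxcl3, Timp1, Igj, Cd8a, Cd8b1, Tox, Serpina1a and Serpina1d, at adjusted p = 0.0503 to 0.136. It gave a call for other extracellular matrix (0.0386) and moved counts of list members as given in the report. No other call of a gene or list named for these 2 comparisons changed. With the block and an estimated correlation the signature gave 0.878 (fell, day 5). For the signature, the genes that rose gave 0.0307 at day 5 and 4.86e-15 at day 10 without the 2 libraries and 0.907 at day 10 with no filter, and those that fell 8.95e-08 (0.15 and 0.349 at day 10 with an estimated correlation) and, with RLE factors, 0.898. Calls of lists went from 187 to 10 with an estimated correlation, 3 with it and the block and 51 with it and without the 2 libraries. With fry, which tests a list by itself, they went to 156. Fry called 13, 0 and 3 lists for KO against WT at days 0, 5 and 10, and 6 and 14 for the interactions at days 5 and 10. For day 10 against day 5 it called 13 in WT and 1 in KO. Without the 2 libraries, lists in KO against WT at day 10 turned to the other direction: myofibroblast 0.514, TGF-beta 0.00617, metalloproteinases 0.989, endosomal sensing 1.32e-04, macrophage 0.00561, chemokines 8.27e-06, complement 2.13e-04, proximal tubule 0.0108, loop 0.315, cell cycle 1.54e-07 and fatty acid oxidation 0.609 (adjusted p; with an estimated correlation myofibroblast 0.899, metalloproteinases 0.995, endosomal sensing and chemokines 0.0856, macrophage 0.462, proximal tubule 0.659, loop 0.82, fatty acid oxidation 0.908, TGF-beta 0.191, complement 0.0856 and cell cycle 0.134); so did interferon response 0.00131 (0.0108 to 0.824 with 1 library left out), dendritic cell 0.0157, endothelium 0.0129 and cell cycle 2.32e-04 in day 10 against day 5 in WT (0.427 to 0.497 with an estimated correlation), Tgfbi there (-0.10) and Cxcl2 in KO against WT at day 10 (0.27). Serpina1e turned on FPKM at day 0 (-2.83, -3.77 and -2.83) and day 5 (-0.65, -0.81 and -0.65). Leaving out 1 library at a time gave 296 to 702, 9 to 1935 and 23 to 2045 genes for KO against WT at days 0, 5 and 10, 359 to 4515 and 0 to 12 for day 10 against day 5 in WT and KO, and 27 to 884 and 246 to 1808 for the interactions. Pld4 ranged from -1.60 to -1.11 at day 5 and from -1.31 to -0.90 at day 10. For the signature the adjusted p ranged from 0.130 to 0.944 and 4.02e-05 to 0.944 (rose and fell, day 5) and from 2.21e-06 to 0.986 and 5.69e-13 to 0.986 (day 10), with turned directions at 0.0239, 0.00856, 0.0453 and 0.0453. The cause of these changes was not tested beyond the libraries named.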

Other observations

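The values here belong to no comparison and were chosen after the data were seen. Slc34a1, a phosphate transporter of the proximal tubule, stood at 8570 CPM ± 775 (SD, n = 4) in WT and 7004 ± 1475 in KO at day 0, and at 26.2 and 187 CPM in WT day 10 replicates 2 and 3. Gm15446 had no count in any of the 12 WT libraries and 65, 66 and 123 counts over KO at days 0, 5 and 10. The haemoglobin genes Hbb-b1 and Hba-a1 are listed at 0 in all 24 libraries. The ribosomal precursor Rn45s took 2.59% of the counts in WT day 10 replicate 1 and 0.959% or less in every other library.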
